A study of Mus musculus with 14 samples.

How the data were processed

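RNA of mouse epidermal bulge and interfollicular cells, G9a WT and cKO, was extracted with TRizol, amplified as cDNA, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are log2 signals per probe set made by the authors with RMA, which corrects background, normalises quantiles between arrays and summarises the probes of a set; the version of RMA and any further adjustment are not given in the sources used here. How the bulge and interfollicular cells were separated is also not given there. The table held 45141 probe sets on 14 arrays, and all per-sample columns were matched to their samples. The 14 arrays formed 4 groups: bulge cKO (n = 4), bulge WT (n = 3), interfollicular cKO (n = 4) and interfollicular WT (n = 3).

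Probe sets were joined to genes by Entrez identifier. A single symbol was found for 28898 probe sets, 551 had several symbols and 15692 had none; 28689 took the symbol of the reference annotation and 209 kept that of the platform. Each of the 17097 genes was represented by the probe set with the highest mean signal over all arrays, which chose among several for 7180 genes. Probe sets without a single symbol were left out of the gene tests and no filter on dim probe sets was used.

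All arrays entered a single model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, residual degrees of freedom 10), so the groups shared one estimate of the spread. The comparisons were cKO against WT in bulge cells, the same in interfollicular cells, the difference of these effects, and bulge against interfollicular cells in WT. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes, and the threshold was an adjusted p under 0.05 with no fold minimum. The overlap of calls was tested with Fisher's exact test in each direction against all genes tested. Standard errors are those of limma.

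A set of 26 gene lists with 446 entries, of which 403 were measured, was fixed before the data were examined, as were the model, the threshold, the alternatives and the rule for named genes, except where a comparison is said to have been chosen after seeing the data. The lists held bulge stem cell, upper follicle and junctional zone, basal keratinocyte, epidermal differentiation, anagen hair, sebaceous and lipid, fibroblast, Langerhans and antigen presenting cell, T cell, melanocyte, endothelial, skeletal muscle and Merkel cell markers. They also held genes of the cell cycle, DNA repair, p53 targets, H3K9 methylation and silencing, germline, imprinting, interferon response, wound and stress, immediate early response, circadian clock, Wnt targets, epithelial to mesenchymal transition and oxidative phosphorylation. Wif1 was in the bulge and Wnt lists and Lef1 in the anagen and Wnt lists. Each list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison.

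The rule named Ehmt2 and Ehmt1, and for each comparison the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, without the last condition for the difference of effects. It added up to 4 members of each described list with the smallest p-values and 8 markers of the compartments; gene models without a proper name were ranked but not named. Snurf and the genes given per array were chosen after their values were seen. So was giving a gene from the top of a comparison in another comparison too.

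The alternatives were cyclic loess, median centring, a filter on dim probe sets, the mean of a gene's probe sets, the probe set with the largest interquartile range, every probe set tested by itself, an intensity trend with robust fitting, array weights, only the groups compared, a fold minimum of 1.5, an adjusted p under 0.1, a block for replicate number, and leaving out each replicate. Leaving out cKO replicates 2 and 3 of both compartments together was added after seeing the data. The model was tested on simulated data, with the arrays of these groups carrying added changes: a log2 change of 1 was recovered for 92.5% of 67 genes in bulge, 91% in interfollicular cells and 89.6% between compartments, with 10, 9 and 7 false calls. In this simulation genes varied independently, each with the same spread in every group. Its false calls therefore do not cover shifts that many genes share on an array. As a check of quality, the 3' minus 5' signal of Gapdh lay between -0.05 and 0.03 on all arrays, and the correlation between arrays of a group lay between 0.982 and 0.998. The 3' minus 5' signal of beta-actin differed between the compartments, from -0.66 to -0.57 on bulge arrays and from -0.56 to -0.45 on IFE arrays. Eif2s3y, on the Y chromosome, read 8.64 to 9.02 and Xist 4.99 to 5.56 on all arrays. Figures were drawn with matplotlib 3.10.9.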

Results

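Gene expression was measured on 14 arrays in epidermal cells of mice aged 15 weeks whose skin was in homeostasis. The mice were wild type (WT) or carried a conditional knockout (cKO) of G9a, the histone H3 lysine 9 methyltransferase encoded by Ehmt2. Cells of the bulge, the region of the hair follicle that holds its stem cells, gave 4 cKO and 3 WT arrays. Cells of the interfollicular epidermis (IFE) gave 4 cKO and 3 WT arrays. Each array held log2 signals per probe set, with a median between 5.76 and 5.84. Arrays have no read depth, so the number of arrays limits the precision. The labels do not say whether the replicates were separate animals, so each p-value measures the spread between samples only. The first principal component held 72.5% of the variance and separated the compartments, with IFE arrays between 23 and 40.1 and bulge WT arrays between -48.2 and -42.4. Bulge cKO replicates 2 and 3 lay at -6.9 and -11.3 on it, and bulge cKO replicates 1 and 4 at -36.7 and -37.2.

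Ehmt2 itself was lower in cKO cells of both compartments on one of its probe sets. On this probe set the signal was 9.63 ± 0.10 (SD, n = 3) in bulge WT and 5.95 ± 0.07 (SD, n = 4) in bulge cKO, a log2 difference of -3.68 (SE 0.06, limma adjusted p = 1.78e-11). In IFE the same probe set gave 9.67 ± 0.10 (SD, n = 3) in WT and 6.01 ± 0.06 (SD, n = 4) in cKO, a log2 difference of -3.66 (SE 0.06, limma adjusted p = 1.89e-11). The cKO levels lay just above the array medians and were not tested against background, so no fold is given. Every cKO array lay between 5.85 and 6.09 and every WT array between 9.51 and 9.78. The other Ehmt2 probe set, which had the higher mean signal over all arrays, had log2 differences of 0.01 in bulge (adjusted p = 0.957) and 0.08 in IFE (adjusted p = 0.722). By the rule of the highest mean, this unchanged probe set stood for Ehmt2 in the gene tests. Ehmt2 is therefore not among the genes counted below as changed between cKO and WT. Where each probe set lies relative to the deleted part of the gene is not given in the sources used here. Ehmt1, which encodes the partner methyltransferase GLP, had log2 differences of -0.19 in bulge (adjusted p = 0.28) and -0.09 in IFE (adjusted p = 0.847).

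**Figure D1:**
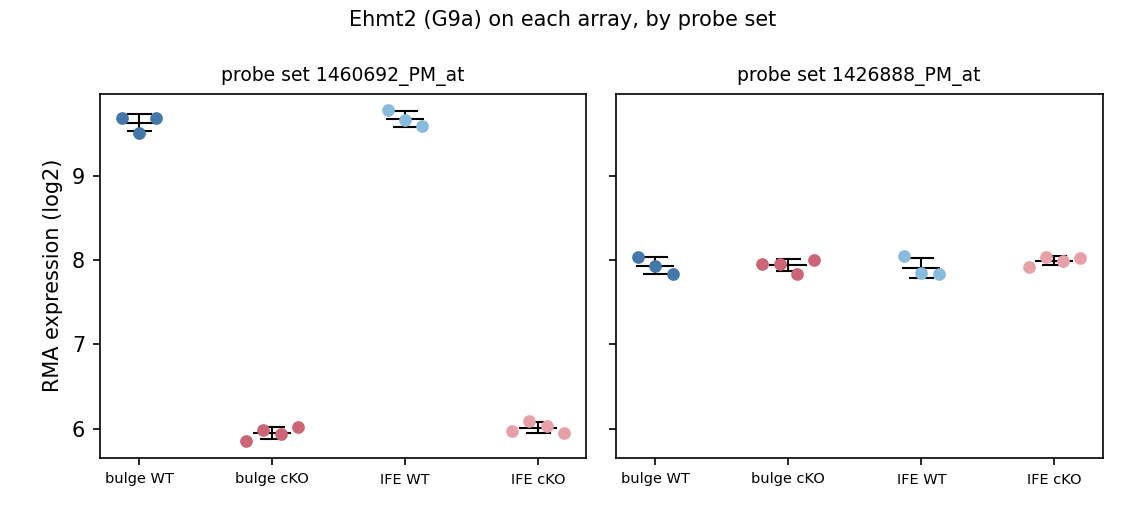
Log2 signal of the 2 Ehmt2 probe sets on each array, by compartment and genotype; points are arrays and bars are the mean ± SD. In the left panel every cKO array lies between 5.85 and 6.09 and every WT array between 9.51 and 9.78.

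In WT skin the bulge and interfollicular cells differed in the genes that mark these compartments. Cd34, a surface marker of bulge stem cells, was higher in bulge cells (log2 difference 6.05, SE 0.43, n = 3 and 3, limma adjusted p = 4.49e-06), as was Lgr5, a receptor of R-spondins on follicle stem cells (log2 difference 5.77, SE 0.42). The IFE WT arrays read 5 to 5.12 for Cd34 and 4.51 to 4.92 for Lgr5, below the array medians. Whether such levels lie above background was not tested, so these differences are not given as folds of transcript. Shisa2 (log2 difference 5.81), Gfra1 (5.48), the BMP antagonist Grem1 (5.24) and the transcription factor Lhx2 (5.24) followed. Next came Col8a2 (5.14), Sema3e (5.13), Nrep (5.08) and Plpp1 (4.78). The genes most in favour of interfollicular cells were Plcxd2 (-4.33), Slc24a3 (-4.31), Clca3a2 (-4.31), the cytokine Il33 (-4.3) and the EGF receptor ligand Epgn (-4.27). They also included Serpinb2 (-4.18), Clca2 (-4), the desmosomal cadherin Dsg1a (-3.95), Robo1 (-3.91) and Ifi202b (-3.9). Krt15 was higher in bulge cells (1.11), whereas Itga6 (-0.87) and the suprabasal keratins Krt1 (-2.5) and Krt10 (-1.74) were lower. The basal keratins had log2 differences of 0.09 for Krt5 (adjusted p = 0.122) and -0.2 for Krt14 (adjusted p = 0.0908).

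All 19 measured bulge stem cell markers were higher in bulge cells, over all genes and adjusted over the list alone, with Sfrp1 at 3.19 and Dkk3 at 3.85. Their camera adjusted p was 2.81e-16, and adjusted p = 0.377 with an estimated correlation. Of 28 cell cycle genes, 23 were lower in bulge cells and 24 when adjusted over the list alone, Cdc20 by a log2 difference of -1.65 and Pcna of -0.49. This list had a camera adjusted p = 8.42e-07, and adjusted p = 0.774 with an estimated correlation. Wound and stress keratinocyte genes were lower for 9 of 13 members, also 9 adjusted over the list alone, among them Krt16 (-2.35) and Hbegf (-1.77). They had a camera adjusted p = 0.00279, and adjusted p = 0.377 with an estimated correlation. Of 23 epidermal differentiation genes, 12 were lower and 1 higher, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00479, adjusted p = 0.774 with an estimated correlation). Ovol1 (-2.56) and Sprr1a (-2.39) were among the lower ones and Calml3 (4.06) was the higher one.

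The remaining lists did not pass camera between the compartments (adjusted p from 0.0781 to 0.866), although single members differed. Among them the median and the mean differed in sign for anagen hair (-0.03 and 0.04), germline (-0.01 and 0.08), clock (0.03 and -0.13) and melanocyte genes (-0.07 and 0.15). Immediate early genes passed without bulge WT replicate 2 or 3 or IFE WT replicate 3 (adjusted p = 0.0339, 0.00459 and 0.0218). Without IFE WT replicate 3 imprinted (0.0355), oxidative phosphorylation (0.00656) and fibroblast genes (0.0218) passed too. These calls used the preset correlation. All arrays with an estimated one gave a camera adjusted p of 0.774 for immediate early and oxidative phosphorylation genes and of 0.377 for imprinted and fibroblast genes. The p53 targets Pmaip1 (-3.65) and Gadd45a (-2.26), the clock genes Bhlhe40 (-2.64) and Hlf (-1.3) and the follicle gene Plet1 (-1.46) were lower in bulge cells. The Wnt target Apcdd1 (-3.12), the surface protein Thy1 (-3.41) and the MHC class II gene H2-Ab1 (-1.69) were lower too. The imprinted genes Sgce (2.96), Peg3 (2.39), Slc38a4 (2.36) and Snrpn (1.08) were higher in bulge cells. So were the collagen genes Col6a1 (4.09) and Col6a2 (3.15), and Mitf (2.88), Wif1 (3.76) and Gli1 (1.49). In total 5998 of 17097 genes passed, 3152 higher and 2846 lower in bulge cells, against 2730 and 3695 with each array centred on its median. In 5879 of these genes the groups did not overlap, as in 47.4% of all genes, where chance gives 10%. All 50 named calls were kept without any single replicate.

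The bulge comparison asked which genes differ between cKO and WT in bulge cells. Minar2 rose from 5.50 ± 0.17 (SD, n = 3), below the array medians, to 8.89 ± 0.35 (SD, n = 4), a log2 difference of 3.38 (SE 0.25, adjusted p = 2.57e-05). Its probe set is of a type that can share probes with other transcripts. Gpa33, which encodes the cell surface antigen A33, rose from 6.39 ± 0.10 (SD, n = 3) to 9.63 ± 0.24 (SD, n = 4; log2 difference 3.25, adjusted p = 2.71e-08). The metalloprotease gene Tll1 fell by 2.58 on the log2 scale, from 7.27 ± 0.37 (SD, n = 3) to 4.69 ± 0.44 (SD, n = 4; adjusted p = 0.000503), and the protease inhibitor gene Serpina3n fell by 2.23 to 5.55 (adjusted p = 0.000122). Both cKO means lay below the array medians, so the size and order of these falls depend on the background. In all, 656 of 17097 genes passed the threshold, 339 higher and 317 lower in cKO, and 91 of them changed at least 2-fold, 63 higher and 28 lower.

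Other genes that rose most were the phospholipase gene Pla2g4f (log2 difference 2.64), the aldo-keto reductase gene Akr1c12 (2.61), and the epidermal lipid transporter Abca12 (2.41). The MHC class II gene H2-Ab1 (2.35), the metallothionein Mt4 (2.35), the cornification protease Casp14 (2.32) and Tcim (2.24) came next. Slc38a4 (2.12), Tspan8 (2.16), Akr1c13 (2.23), Trim30d (1.74), Efcab1 (1.32) and Adgrv1 (1.26) rose too. Whether the probe sets of the related genes Akr1c12 and Akr1c13 read each other's transcripts could not be checked. The genes that fell most after Tll1 and Serpina3n were the lipid phosphatase Plpp3 (-1.72), the potassium channel Kcnma1 (-1.59), and the homeobox gene Hoxb6 (-1.58). Igsf10 (-1.56), the peptidase Mme (-1.52), Enc1 (-1.38), the connective tissue growth factor Ccn2 (-1.35) and the prostaglandin dehydrogenase Hpgd (-1.33) were the next lower. Nop53 (-0.83), Flrt3 (-0.76) and Dio2 (-0.32) fell as well.

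Of 23 epidermal differentiation genes, 3 rose in bulge cKO cells over all genes and 16 adjusted over the list alone, with a median log2 difference of 1.06. The camera adjusted p was 3.12e-07, and adjusted p = 0.545 with an estimated correlation. The 3 genes were Casp14, the cornified envelope gene Sprr1a (1.53) and the transcription factor Ovol1 (1.18), while Ivl had 1.01 (adjusted p = 0.0616). Krt1, whose 3 bulge WT arrays lay between 9.41 and 9.87, read 9.36, 11.93, 11.75 and 11.31 on bulge cKO replicates 1 to 4. The 19 measured bulge stem cell markers had a median of -0.53, with 0 past the threshold over all genes and 4 lower adjusted over the list alone. Camera gave them an adjusted p = 2.67e-06, and adjusted p = 0.545 with an estimated correlation. The median without cKO replicates 2 and 3 was -0.16 for these markers (camera adjusted p = 0.0215), 0.47 for the differentiation genes (6.65e-06) and -0.15 for the basal keratinocyte genes (0.00026). Tcf7l2 had -0.43 (adjusted p = 0.0646), Wif1 -1.81 (0.0666), Nfatc1 -0.57 (0.0885), Lgr5 -1.22 (0.0933) and Cd34 -0.73 (0.272). Cd34 read 9.84 and 9.95 on bulge cKO replicates 2 and 3, 10.55 and 11.18 on replicates 1 and 4, and 10.93 to 11.43 on the WT arrays. Of 11 basal keratinocyte genes, the adhesion genes Lama3 (-0.4) and Itgb4 (-0.36) fell, and 7 were lower adjusted over the list alone (median -0.28, camera adjusted p = 0.000374, adjusted p = 0.522 with an estimated correlation).

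Markers of Langerhans and other antigen presenting cells were higher in bulge cKO, 5 of 11 over all genes and 11 adjusted over the list alone (median 0.56, camera adjusted p = 3.12e-07, adjusted p = 0.522 with an estimated correlation). Among them were the MHC class II genes H2-Ab1, H2-Eb1 (0.97) and H2-Aa (0.76) and the invariant chain Cd74 (0.87). Of 11 T cell markers, 0 passed over all genes and 6 were higher adjusted over the list alone (median 0.33, camera adjusted p = 0.0146, adjusted p = 0.613 with an estimated correlation). Cd3g had a log2 difference of 1.28 (adjusted p = 0.0712) and Nkg7 of 0.57 (adjusted p = 0.0558). Cd3g read 7.03 and 7.29 on bulge cKO replicates 2 and 3, 5.79 and 6.62 on replicates 1 and 4, and 5.13 to 5.62 on bulge WT arrays. Leaving out cKO replicates 2 and 3 gave a median of 0.33 for the Langerhans list (camera adjusted p = 9.23e-09) and of 0.15 for the T cell list (0.0471).

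Wound and stress keratinocyte genes had a median of 0.32, and Hbegf, an EGF receptor ligand, rose (1.05). It was the 1 of 13 members past the threshold, with 5 higher adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.522 with an estimated correlation). The mean signal of this list was 6.44, 7.23, 7.29 and 6.94 on bulge cKO replicates 1 to 4 against 6.31 to 6.45 on the WT arrays, and without cKO replicates 2 and 3 its median was 0.14 (camera adjusted p = 0.0177). Of 18 immediate early genes, Egr2 rose (1.05), and 3 were higher adjusted over the list alone (median 0.21, camera adjusted p = 0.00624, adjusted p = 0.713 with an estimated correlation). Of 20 p53 targets, the apoptosis gene Pmaip1 (1.86), Gadd45a (0.98) and the cell cycle inhibitor Cdkn1a (0.82) rose, also 3 adjusted over the list alone (median 0.16, camera adjusted p = 0.0322, adjusted p = 0.522 with an estimated correlation). The 12 sebaceous and lipid genes had a median of 0.28, with Pparg higher (0.37) and 3 adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.667 with an estimated correlation). The interferon response list had a median of 0.19 over 23 genes and a camera adjusted p of 0.0286 upward (adjusted p = 0.623 with an estimated correlation). Its 1 gene past the threshold, over all genes and adjusted over the list alone, was Usp18, which fell by 0.58. Medians without cKO replicates 2 and 3 were 0.23 for immediate early genes (camera adjusted p = 0.00187), 0.1 for p53 targets (0.00765), 0.19 for sebaceous genes (0.0369) and 0.09 for the interferon list (0.0471). Single libraries changed some calls, with a camera adjusted p for p53 targets of 0.129 without cKO replicate 4 and 0.055 without WT replicate 1. It was 0.496 for immediate early genes without WT replicate 1 and 0.0724 for the interferon list without WT replicate 3.

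Imprinted genes moved in both directions. Of 17 members Slc38a4, Snrpn (0.66) and Ndn (0.41) rose and 2 fell, among them Sgce (-0.95). Adjusted over the list alone, 4 rose and 4 fell (median -0.01, mean 0.09, camera adjusted p = 0.876, fry mixed adjusted p = 1.72e-10). Mixed fry counts changes in either direction and passed for other lists too, such as germline (adjusted p = 0.000996) and basal keratinocyte genes (0.00244). Fry for a shift in a single direction passed for p53 targets (adjusted p = 0.0102) and for basal, wound and Langerhans genes (0.0179 each). It did not pass for bulge stem cell (0.112), differentiation (0.0567), sebaceous (0.123), T cell (0.107), interferon (0.112) or immediate early genes (0.191). Of 8 genes of the upper follicle and junctional zone, the P-cadherin gene Cdh3 fell by 0.5, and 4 were higher and 1 lower adjusted over the list alone (median 0.39, camera adjusted p = 0.651). Of 20 germline genes, Rhox5 rose (0.39) and Piwil2 fell (-0.5), or 2 and 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.651). Of 15 genes of the epithelial to mesenchymal transition, the metalloproteases Mmp2 (-1.3) and Mmp14 (-0.51) fell and Twist1 rose (0.15). Adjusted over the list alone, 4 fell and 3 rose (median 0.07, mean -0.13, camera adjusted p = 0.99). Hlf (0.72) was past the threshold among 15 clock genes, with 2 higher and 1 lower adjusted over the list alone. Ccnd1 (-0.41) was so among 12 Wnt targets, with 1 higher and 2 lower adjusted over the list alone. Emcn (0.28), Krt20 (0.26) and Krt31 (0.19) were the single higher members of the endothelial, Merkel cell and anagen hair lists, over all genes and adjusted over the list alone.

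Lists of cell cycle (median 0.09, camera adjusted p = 0.989), DNA repair (-0.08, 0.172), the H3K9 methylation and silencing machinery (-0.09, 0.068) and oxidative phosphorylation (-0.03, 0.792) had 0 members past limma's threshold, over all genes and adjusted over the list alone, where 4390 genes had an unadjusted p under 0.05. The silencing machinery passed camera downward without cKO replicate 1, cKO replicate 3 or WT replicate 1 (adjusted p = 0.0455, 0.0386 and 0.0191). These calls used the preset correlation, and all arrays with an estimated one gave this list a camera adjusted p of 0.545. Fibroblast markers (median 0.04, mean -0.02, camera adjusted p = 0.991), melanocyte markers (0.05, -0.02, 0.651) and skeletal muscle markers (0, 0.02, 0.876) had 0 past over all genes. Adjusted over the list alone they had 0 fibroblast, 1 lower melanocyte and 1 higher muscle gene. Median log2 difference and camera adjusted p were 0.07 and 0.651 for anagen hair, 0.03 and 0.855 for the clock, and 0.03 (mean -0.06) and 0.99 for Wnt targets. They were -0.01 (mean 0.03) and 0.876 for endothelial and 0.04 and 0.329 for Merkel cell markers.

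In 638 of the 656 genes called in bulge cells the groups did not overlap, as in 18.5% of all genes, where chance gives 5.71%. With each array centred on its median 564 genes passed, 234 higher and 330 lower. With only the bulge arrays in the model 72 passed, 41 higher and 31 lower, and 66 of the 656 were kept, so the count rests on the estimate of spread and the degrees of freedom that the interfollicular arrays add. The count depended on single libraries, with 212 and 185 genes without cKO replicates 2 and 3, 116 and 134 without WT replicates 1 and 2, 987 without cKO replicate 1 and 2553 without cKO replicate 4. Of the 56 named calls, 50, 28 and 25 were kept without cKO replicates 1, 2 and 3, and 20, 19 and 44 without WT replicates 1, 2 and 3. The 18 kept without any single replicate were Minar2, Gpa33, Pla2g4f, Akr1c12, Abca12, Tcim, Tll1, Serpina3n, Plpp3, Kcnma1, Mme, Enc1, Slc38a4, Snrpn, Tspan8, Akr1c13, Trim30d and Nop53. Without cKO replicates 2 and 3 of both compartments together, a comparison chosen after seeing the data, 80 genes passed, 60 higher and 20 lower, and 68 of the 656 were kept.

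**Figure D2:**
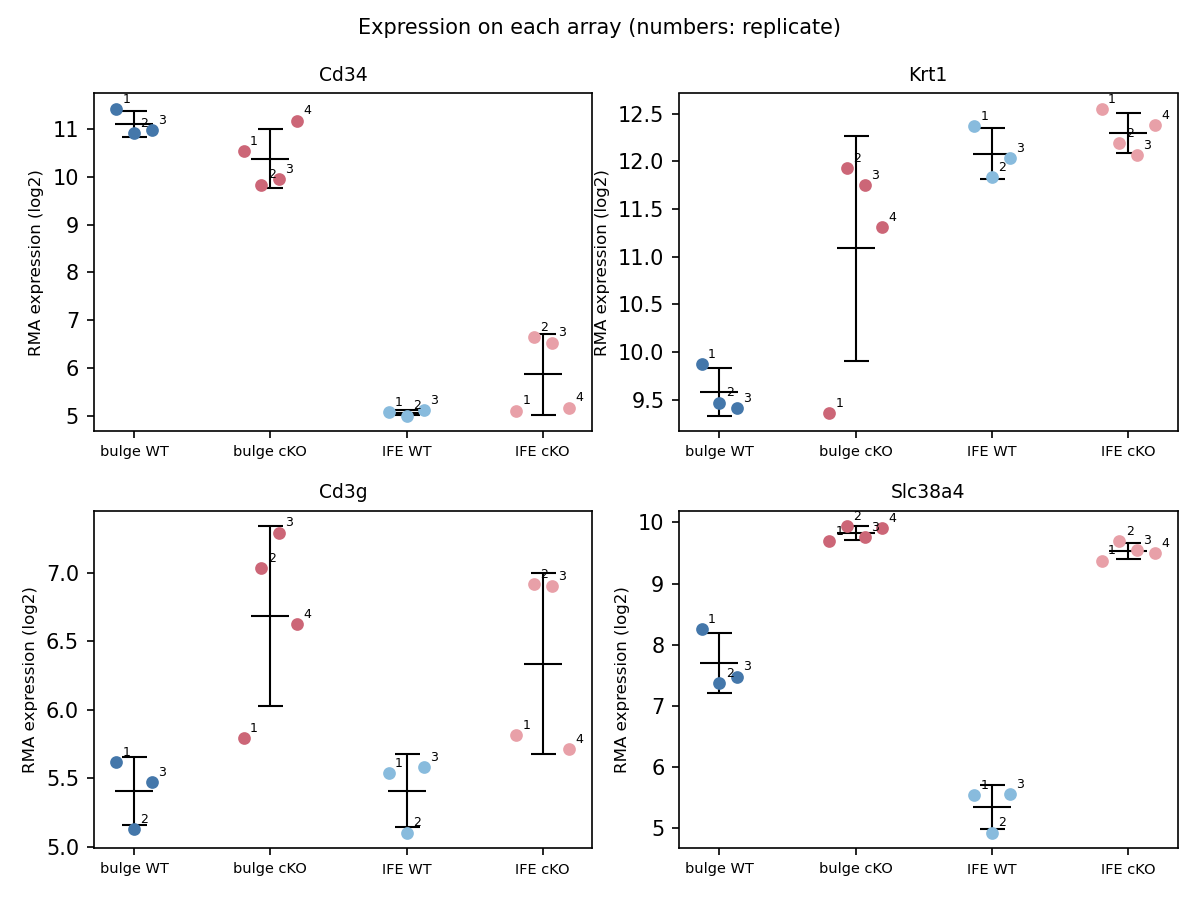
Log2 signal of Cd34, Krt1, Cd3g and Slc38a4 on each array, by compartment and genotype; points are arrays with their replicate number and bars are the mean ± SD. Cd3g reads 7.03 and 7.29 on bulge cKO replicates 2 and 3 and 6.91 and 6.9 on IFE cKO replicates 2 and 3.

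In interfollicular cells Minar2, Slc38a4 and Akr1c12 had the largest positive log2 differences, each from a WT level below the array medians, so their folds and their order depend on the background. Minar2 went from 3.45 ± 0.09 (SD, n = 3), near the lowest values on the arrays (3.18 to 3.22), to 7.79 ± 0.52 (SD, n = 4; log2 difference 4.35, SE 0.25, adjusted p = 1.4e-06). The amino acid transporter gene Slc38a4, which is imprinted, went from 5.35 ± 0.36 (SD, n = 3) to 9.53 ± 0.13 (SD, n = 4; log2 difference 4.18, adjusted p = 3e-07), and Akr1c12 had a log2 difference of 3.21 (adjusted p = 2.82e-08). The matrix metalloprotease gene Mmp3 fell by 1.61 on the log2 scale (SE 0.26, adjusted p = 0.0173) and the hyaluronan synthase gene Has3 fell by 1.28 (SE 0.17, adjusted p = 0.00316). In all, 85 of 17097 genes passed, 55 higher and 30 lower in cKO, and 22 of them changed at least 2-fold, 20 higher and 2 lower.

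The other genes that rose most were Tspan8 (log2 difference 3.04), Gpa33 (2.87), the gasdermin gene Gsdmc2 (2.55), the adhesion receptor Adgrv1 (2.41), Akr1c13 (2.39), Efcab1 (2.21) and Trim30d (2.2). Among the genes that fell were Nop53 (-0.96), a ribosome biogenesis factor, Flrt3 (-0.86), and the sialyltransferase St3gal1 (-0.76). The deiodinase Dio2 (-0.75), the growth factor gene Gdnf (-0.72), Rrp1b (-0.66), the cytokine gene Tslp (-0.66) and the activin subunit gene Inhba (-0.64) fell too. Of 17 imprinted genes, Slc38a4 and Snrpn (1.37) rose over all genes, and 2 rose and 1 fell adjusted over the list alone (median 0, mean 0.33, camera adjusted p = 0.118, fry mixed adjusted p = 6.9e-10). The germline gene Rhox5 had 0.36 (adjusted p = 0.0547).

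In the other lists 0 members passed limma's threshold over all genes in interfollicular cells, where 1876 genes had an unadjusted p under 0.05. Sebaceous and lipid genes lay higher as a group (median 0.38 over 12 genes, 1 adjusted over the list alone, camera adjusted p = 5.28e-06, adjusted p = 0.505 with an estimated correlation), with Plin2 at 0.56 (adjusted p = 0.0979). Epidermal differentiation genes lay higher (median 0.3 over 23 genes, 1 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.751 with an estimated correlation), with Calml3 at 1.59 (adjusted p = 0.12). Basal keratinocyte genes lay lower (median -0.16 over 11 genes, 5 adjusted over the list alone, camera adjusted p = 0.000171, adjusted p = 0.476 with an estimated correlation), with Itga6 at -0.31 (adjusted p = 0.207). Cell cycle genes lay lower on average (median -0.27 over 28 genes, 0 adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.754 with an estimated correlation), with Mcm6 at -0.29 (adjusted p = 0.481). The mean signal of the cell cycle list was 8.2, 8.29 and 7.47 on IFE WT replicates 1 to 3. It was 7.64, 7.49, 7.61 and 8.21 on IFE cKO replicates 1 to 4, so WT replicate 3 lay below every cKO array. The p53 targets lay higher (median 0.14 over 20 genes, 1 adjusted over the list alone, camera adjusted p = 0.00593, adjusted p = 0.303 with an estimated correlation), with Rrm2b at 0.3 (adjusted p = 0.054). The differentiation genes (median 0.14, camera adjusted p = 0.0509) and the cell cycle genes (-0.07, 0.62) no longer passed without cKO replicates 2 and 3. Sebaceous genes (0.21, 0.000716), basal keratinocyte genes (-0.16, 0.00111) and p53 targets (0.15, 0.000178) did. Fry for a shift in a single direction, with all arrays, passed in interfollicular cells for imprinted genes only (adjusted p = 0.00409). It gave 0.172 for sebaceous, 0.495 for differentiation and for cell cycle genes, and 0.0756 for basal keratinocyte genes and for p53 targets. Langerhans markers had 0.409, T cell markers 0.38 and bulge stem cell markers 0.575 by fry. Of single libraries, cKO replicate 2 and WT replicates 1 and 2 decided the cell cycle call (camera adjusted p = 0.0532, 0.0684 and 0.527 without them). Without WT replicate 2 the differentiation genes had 0.0512 and the p53 targets 0.0647.

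Langerhans cell markers (median 0.33, camera adjusted p = 0.000121, adjusted p = 0.637 with an estimated correlation) and T cell markers (median 0.19, camera adjusted p = 0.00251, adjusted p = 0.615 with an estimated correlation) lay higher in interfollicular cKO, each with 0 of 11 genes adjusted over the list alone. Cd3g had a log2 difference of 0.93 (adjusted p = 0.379) and Cd3e of 1.08 (adjusted p = 0.388), and Cd3g read 6.91 and 6.9 on IFE cKO replicates 2 and 3. Bulge stem cell markers also lay higher (median 0.17, 0 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.754 with an estimated correlation), with Krt15 at 0.29 (adjusted p = 0.293) and Cd34 at 0.8 (adjusted p = 0.517). Cd34 read 6.65 and 6.53 on IFE cKO replicates 2 and 3 and 5 to 5.16 on every other IFE array, and without these libraries the list lay at a median of -0.07 (camera adjusted p = 0.674). Interferon response (median 0.07, camera adjusted p = 0.0132, adjusted p = 0.637 with an estimated correlation) and immediate early genes (median 0.14, camera adjusted p = 0.0168, adjusted p = 0.754 with an estimated correlation) lay higher, each with 0 adjusted over the list alone. The Langerhans (median 0.14, camera adjusted p = 0.0509) and immediate early lists (0.16, 0.0509) no longer passed without cKO replicates 2 and 3. The T cell (0.14, 0.00894) and interferon lists (0.1, 0.000178) did, and endothelial markers passed downward (-0.08, 0.0204). Without single libraries the camera adjusted p was 0.0868 and 0.203 for bulge stem cell markers (cKO replicates 2 and 3) and 0.0963 (WT replicate 1). It was 0.324 and 0.0665 for the interferon list (cKO replicate 4 and WT replicate 3) and 0.0843 and 0.283 for immediate early genes (cKO replicate 1 and WT replicate 3). Lists that passed only without a library were endothelial markers (0.0378 without cKO replicate 2 and 0.0297 without WT replicate 1) and, without WT replicate 3, DNA repair (0.00775), imprinted genes (0.048) and oxidative phosphorylation (0.00897). With all arrays and an estimated correlation the camera adjusted p of these lists was 0.751, 0.769, 0.615 and 0.953 in this order. Among the lists that did not pass camera in interfollicular cells, the median and the mean differed in sign for the upper follicle (-0.07 and 0.1), for the mesenchymal transition (0.02 and -0.12; Snai2 at -0.98, adjusted p = 0.0963) and for melanocytes (0.05 and -0.03).

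In each of the 85 genes called in interfollicular cells the groups did not overlap, as in 11% of all genes, where chance gives 5.71%. With only the interfollicular arrays in the model 48 passed, 36 higher and 12 lower, and 41 of the 85 were kept. The count was 43 without IFE cKO replicate 3 and 38 without IFE WT replicate 1. Of the 21 named calls, 17 were kept without any single replicate, while Mmp3, Flrt3, St3gal1 and Inhba were lost without WT replicate 1 and all of these but Flrt3 without cKO replicate 3. St3gal1 was also lost without cKO replicate 1, cKO replicate 2 or WT replicate 2, Mmp3 without cKO replicate 2 or WT replicate 3, and Inhba without WT replicate 3. Without cKO replicates 2 and 3 of both compartments together, 41 genes passed, 38 higher and 3 lower, and 29 of the 85 were kept.

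The genes changed in both compartments moved the same way in each. They numbered 43, 34 of them higher in cKO (1.09 expected if the calls were independent, Fisher's exact p = 1.39e-44) and 9 lower (0.556 expected, Fisher's exact p = 2.35e-09). Fisher's test treats genes as independent, which they are not. Both comparisons also share each gene's spread from a single model and may share animals. These p-values and expected counts are therefore descriptions only. By limma's adjusted threshold 0 genes went in opposite directions; the counts at an unadjusted p under 0.05 were 4390 in bulge and 1876 in interfollicular cells. The log2 differences in bulge and interfollicular cells were 3.38 and 4.35 for Minar2, 3.25 and 2.87 for Gpa33, 2.61 and 3.21 for Akr1c12, and 2.16 and 3.04 for Tspan8. They were 2.23 and 2.39 for Akr1c13 and 1.74 and 2.2 for Trim30d. Akr1c12 and Akr1c13 may not be separate observations, as shared signal between their probe sets could not be checked. The imprinted gene Snrpn had 0.66 and 1.37, and Snurf, which shares its transcript, 0.79 and 1.28. Those lower in both included Nop53 (-0.83 and -0.96), Flrt3 (-0.76 and -0.86) and Dio2 (-0.32 and -0.75). Across all genes, which are not independent replicates, the bulge and interfollicular differences had Pearson's r = 0.382 and Spearman's rho = 0.202. The overlap fell to 25 genes without bulge WT replicate 1, 27 without bulge WT replicate 2, 28 without bulge cKO replicate 3 and 26 without IFE WT replicate 1. With only the arrays of each comparison in its model it was 16, and without cKO replicates 2 and 3 together 17 genes, all of these 17 among the 43.

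**Figure D3:**
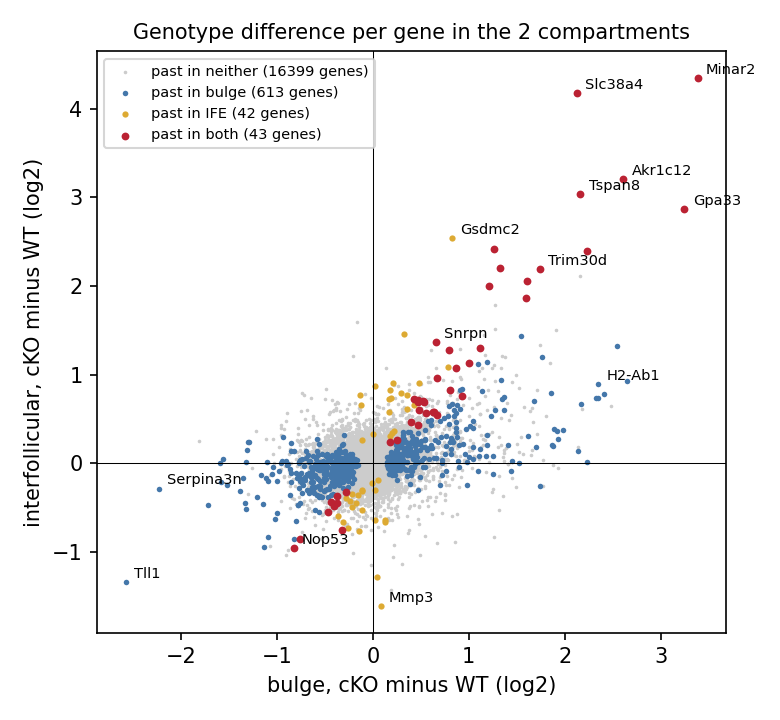
Log2 difference between cKO and WT in bulge cells (x) and in interfollicular cells (y); each point is a gene and colours mark the genes past adjusted p under 0.05 in bulge, in interfollicular cells, in both or in neither. The 43 genes past in both lie in the 2 quadrants where the signs are equal, 34 higher and 9 lower in cKO.

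The genotype effect itself differed between bulge and interfollicular cells for 18 genes, 4 with a more positive effect in bulge cells and 14 with a more negative one. Slc38a4 rose from 7.7 to 9.83 in bulge and from 5.35 to 9.53 in interfollicular cells, a difference of effects of -2.06 (SE 0.28, adjusted p = 0.0228), from a higher WT level in bulge. Serpina3n had means of 7.78 in WT and 5.55 in cKO in bulge and of 5.23 and 4.95 in interfollicular cells (difference of effects -1.95, SE 0.27, adjusted p = 0.0228), and Mme had 7.79 and 6.28 against 5.73 and 5.5 (-1.28, adjusted p = 0.0284). The interfollicular means of Serpina3n and Mme and the interfollicular WT mean of Slc38a4 lay below the array medians, where a fall cannot be read fully and a rise depends on the background. The homeobox gene Hoxa5 (-0.81), Sorcs3 (-0.79), the phosphorylase kinase gene Phka1 (-0.79) and Tenm3 (-0.6) also had a lower effect in bulge cells. Tmem176b (-0.91) had means of 9.2 and 9.97 in interfollicular WT and cKO and of 10.36 and 10.22 in bulge, and the planar polarity gene Vangl2 (-0.63) had 7.96 and 8.28 against 8.9 and 8.59. Tslp (0.79), Dusp26 (0.47) and Slc41a3 (0.44) had the more positive effect in bulge cells, and Snrpn had -0.71 (adjusted p = 0.0572).

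Bulge stem cell markers had a lower effect in bulge than in interfollicular cells as a group (median -0.63 over 19 genes, 0 past over all genes and 2 adjusted over the list alone, camera adjusted p = 1.55e-08, adjusted p = 0.768 with an estimated correlation), with Tcf7l2 at -0.58 (adjusted p = 0.212) and Krt15 at -0.48 (adjusted p = 0.212). Their median without cKO replicates 2 and 3 was -0.14 (camera adjusted p = 0.274). Wound and stress genes had a higher one (median 0.66 over 13 genes, 0 over all genes and 4 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.768 with an estimated correlation), with Defb3 at 0.3 (adjusted p = 0.162). Differentiation genes (median 0.51) and Langerhans cell markers (0.45), each with 0 adjusted over the list alone, both had a camera adjusted p = 0.0241, and adjusted p = 0.928 with an estimated correlation. Among their members were Sprr1a at 1.52 (adjusted p = 0.235) and H2-Ab1 at 1.46 (adjusted p = 0.299). Leaving out cKO replicates 2 and 3 gave medians of 0.25 for wound genes (camera adjusted p = 0.00622), 0.33 for differentiation genes (0.0406) and 0.3 for Langerhans cell markers (0.000265). Without single libraries the differentiation genes no longer passed for bulge cKO replicates 2, 3 and 4 (0.0995, 0.0596 and 0.0593), bulge WT replicate 2 (0.141), IFE cKO replicates 1 and 4 (0.241 and 0.0697) and IFE WT replicate 1 (0.179). The Langerhans cell markers had 0.0902, 0.0596, 0.0593, 0.0972, 0.241, 0.0787 and 0.178 without these libraries in the same order, and 0.0875 without IFE WT replicate 3. Cell cycle genes passed without bulge WT replicate 3 (0.0153), IFE cKO replicate 4 (0.000116) or IFE WT replicate 3 (8.58e-08), and immediate early genes without bulge WT replicate 3 (0.0153). These calls used the preset correlation, and all arrays with an estimated one gave both lists a camera adjusted p of 0.928. In lists that did not pass camera, the median and the mean differed in sign for p53 targets (-0.01 and 0.16), the clock (-0.01 and 0.02), the mesenchymal transition (0.08 and -0.01) and oxidative phosphorylation (-0.01 and 0.01). Fry for a shift in a single direction passed for none of the lists in this comparison, with the lowest adjusted p of 0.176 for wound and stress genes. By limma 2404 genes had an unadjusted p under 0.05 for this difference. The calls of Tmem176b, Phka1 and Tenm3 were kept without any single replicate. The count was 3 without bulge cKO replicate 2, bulge cKO replicate 3 or IFE cKO replicate 3, 4 without IFE WT replicate 1 or 2, and 7 without IFE cKO replicate 1. It was 8 without bulge WT replicate 3, 10 and 11 without bulge WT replicates 1 and 2, 11 without IFE WT replicate 3 and 240 without bulge cKO replicate 4. Without cKO replicates 2 and 3 of both compartments together it was 3. Of the named calls, 18 of 56 in bulge, 11 of 21 in interfollicular cells, 7 of 12 for the difference of effects and 20 of 50 between compartments had a group mean below 5.76, the lowest array median.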

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

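The counts of other splits of the samples, the test of the immune markers, leaving out cKO replicates 2 and 3 for the lists, the count of bulge cKO libraries above WT and the mixing fractions with the interfollicular cKO profile were tests chosen only after the result was seen.

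Bulge cKO replicates 2 and 3 lay toward the interfollicular profile, but interfollicular cells alone would give the same mixing fraction from genes high in bulge and from genes high in interfollicular WT cells, whereas 192 bulge-high genes gave 0.64 and 0.56 and 160 interfollicular-high genes 0.35 and 0.31. The smaller gap was 0.25, against at most 0.11 in a left-out WT library (0.27 and 0.28 with the interfollicular cKO profile). The WT libraries had fractions of at most 0.12, so they do not show the gap that mixing gives at higher fractions. Bulge cKO replicate 1 had a gap of 0.2 at a fraction of 0.02 from both classes together. The gaps go against a single shared fraction but do not exclude such cells as the whole cause. Interfollicular cKO replicates 2 and 3 in turn lay toward the bulge on the first principal component (23.3 and 23, other interfollicular arrays 29.8 to 40.1). A mix with further cell types may still be present, and a genotype effect stays open: 4 of 4 bulge cKO libraries lay above every WT library in a fraction from both gene classes together, replicates 1 and 4 with 0.02 and 0.04 against 0.01, but not in each class, where replicate 4 had 0.05 from bulge-high genes (0.12 in WT replicate 3) and replicate 1 had 0.01 from interfollicular-high genes (0.01 in WT replicates 1 and 3). Of the 656 genes called in bulge cells, 14.8% moved away from the interfollicular level, a share between the bounds set for and against interfollicular cells as the cause, and 559 moved toward it. Among the 317 lower genes 252 were higher in bulge WT than in interfollicular WT (58.4 if independent), but the same WT arrays enter both differences. Across all genes these differences had a correlation of -0.641, against -0.534 in simulated unchanged groups. Their covariance was -0.107 against -0.00973, so the shared arrays gave a small part of it in this simulation, where genes varied independently. How much of the excess among the called genes the shared arrays give was not measured.

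Most Langerhans and T cell genes were higher in cKO replicates 2 and 3 of both compartments: 86.4% of 22 markers in bulge and 72.7% in interfollicular cells lay above every WT array in both libraries, against 34.9% and 15.4% of all genes and 10% by chance. Those that did not in interfollicular cells were Cd207 (6 and 5.92 against 5.41 to 6.09 on WT arrays), Thy1 (8.86 and 9.07 against 9.12 to 10.03), Trat1, Gzmb, Il2rb and Cd247. RNA of Langerhans and T cells in these libraries stays a candidate explanation that this test does not decide, since high markers on these libraries had prompted it. H2-Ab1 read 9.42 and 9.01 on bulge cKO replicates 2 and 3, 7.7 and 8.17 on replicates 1 and 4 and 6.05 to 6.55 on WT arrays, and Cd74 read 7.79 and 7.56, 7.09 and 7.1, and 6.4 to 6.61; no gate that would remove such cells is given in the sources used here. In bulge the rise was not confined to replicates 2 and 3, without which the Langerhans list had a median of 0.33 and 0 members past the threshold over all genes. Its camera adjusted p was then 9.23e-09 at the preset correlation, while all arrays with an estimated correlation of 0.81 gave 0.522. In interfollicular cells without replicates 2 and 3 the list had a median of 0.14 and no longer passed (0.0509). More immune cells in cKO skin as an effect of the genotype, or a changed expression in the keratinocytes, stays open and untested, and MHC class II genes alone would not separate these. Linkage to the targeted Ehmt2 locus was tested only for genes changed in both compartments, so for the MHC class II genes it stays untested too.

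The 43 genes changed the same way in both compartments were set against 2 technical explanations. Linkage to the targeted locus would place them near Ehmt2, but 0% were among the 100 measured genes nearest to it, and 2 of 43 lay on its chromosome 17. The cell mixture of cKO replicates 2 and 3 would end the effect without these libraries, but 100% kept their direction with an unadjusted p under 0.05 in both compartments, although the genes had been chosen with the remaining arrays included. The first test argues against linkage near Ehmt2 as the cause of the pattern. The second shows that these differences were present on the other arrays too, and 17 of the 43 genes kept the adjusted threshold in both compartments. Since those arrays had helped to choose the genes, it cannot decide against the cell mixture. An effect of the genotype is a hypothesis that may account for the pattern, while differences between the mouse lines elsewhere in the genome were not tested.

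Of the 35 splits of the bulge arrays into groups of 4 and 3, 2 gave at least the real 656 genes, the highest other with 2621, so chance is not excluded for that count. That split set cKO replicate 4 and the 3 WT arrays against cKO replicates 1 to 3, and several times the real count points to a structure of the samples. Of the 35 splits of the interfollicular arrays, 2 gave at least 85 genes, the highest other with 334, so chance is not excluded there, and this too points to a structure of the samples. For the difference of effects 4 of 100 drawn splits reached 18 genes, the others with 38, 53 and 3985, again a structure of the samples; this share is too close to the bound of 0.05 for 100 draws to exclude chance firmly. For the overlap 1 of 100 splits, the real one, reached 43 genes, with 2 in the highest other. These splits were drawn separately in each compartment, so a grouping of the samples shared by both compartments was not tested as such. Chance is therefore not firmly excluded for the overlap. For the compartments in WT the 10 splits are too few for a share under 0.05, with 5998 genes in the real split and 1 in the highest other.

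The genotype effect, as bulge minus interfollicular log2 difference, differed between the compartments in the test of the difference for Tslp (0.79), Dusp26 (0.47), Slc41a3 (0.44), Slc38a4 (-2.06), Serpina3n (-1.95), Mme (-1.28), Tmem176b (-0.91), Hoxa5 (-0.81), Sorcs3 (-0.79), Phka1 (-0.79), Vangl2 (-0.63) and Tenm3 (-0.6).

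Bulge cKO replicate 4 stood apart from the other bulge cKO arrays for Tll1, with 5.34 against 4.42 to 4.51 (gap over range 0.903), and for Plpp3, with 8.39 against 7.29 to 7.43 (0.869). These were 2 of 121 pairs of gene and group tested, and chance alone sets apart about 1 in 20.

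Among 15588 probe sets without a gene symbol, not counting the array's control probe sets, which the gene comparisons leave out, 522 differed between cKO and WT in bulge cells, 228 higher and 294 lower, and 45 in interfollicular cells, 35 higher and 10 lower. The one with the largest rise in both had log2 differences of 2.52 in bulge and 3.01 in interfollicular cells.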

How the results depend on the processing

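Leaving out cKO replicates 2 and 3 of both compartments together was the test chosen only after seeing the data. The counts of genes for bulge, interfollicular cells, the difference of effects, the compartments and the overlap were 656, 85, 18, 5998 and 43. They stayed within 1.5 times of this under cyclic loess (616, 105, 21, 6493 and 44), median centring (564, 80, 20, 6425 and 38), the mean of probe sets (810, 111, 16, 6303 and 54), the largest interquartile range (632, 108, 18, 6439 and 46) and an intensity trend with robust fitting (768, 90, 13, 6017 and 48). The cause was not tested where other settings moved them, except that thresholds act by construction. Fewer arrays did not act in a single direction, as the bulge count rose to 987 without cKO replicate 1 and to 2553 without cKO replicate 4. For the counts without cKO replicates 2 and 3, the smaller sample and the distinct profile of these libraries were not told apart. Without dim probe sets bulge, interfollicular cells and the difference gave 421, 52 and 5. With every probe set tested the 5 counts were 1646, 173, 65, 15771 and 88. A fold of at least 1.5 gave 224, 53, 11, 2848 and 22. An adjusted p under 0.1 gave 2015, 176, 49 and an overlap of 80, and an unadjusted p under 0.01 an overlap of 191. Only the groups compared gave 72, 48 and an overlap of 16. Array weights gave 8242, 1458, 4974 and an overlap of 519, but their estimation stopped before converging, with a weight of 15.48 for bulge cKO replicate 3, so these values are unreliable. Without cKO replicates 2 and 3 together the counts were 80, 41, 3 and an overlap of 17, and the bulge stem cell list in interfollicular cells turned from higher to lower (camera adjusted p = 0.674).

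Leaving out 1 replicate in turn gave 116 to 2553 genes in bulge, 38 to 107 in interfollicular cells, 3 to 240 for the difference, 4801 to 5538 for the compartments and an overlap of 25 to 53. In bulge the count was 116 without WT 1, 134 without WT 2, 185 without cKO 3, 212 without cKO 2, 987 without cKO 1 and 2553 without cKO 4; in interfollicular cells it was 38 without WT 1 and 43 without cKO 3; for the difference it was 240 without bulge cKO 4 and 3 without bulge cKO 2.

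A block for replicate number gave 31 genes in bulge (4444 at an unadjusted p under 0.05), 0 in interfollicular cells (1151), 0 for the difference (2446) and an overlap of 0 by limma. Whether the numbers pair the samples stays open: after removing group means arrays with the same number correlated by -0.57 to 0.25 between compartments and by -0.62 to 0.18 between genotypes, and 5 of 14 arrays correlated best with their own number in the other compartment. Yet cKO replicates 2 and 3 stood apart in both compartments, with Cd3g at 7.03 and 7.29 in bulge and 6.91 and 6.9 in interfollicular cells, and their opposite shifts along the first principal component would lower such correlations. Pairing was therefore neither shown nor excluded, and these counts are not read as a weaker effect. Of the named genes past the threshold, 18 of 56 in bulge, 17 of 21 in interfollicular cells, 3 of 12 for the difference and 50 of 50 for the compartments kept their call without each single replicate. Signal near the background, with array medians of 5.76 to 5.84, limits what dim genes can show.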

Other observations

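The homeobox genes were singled out after their values were seen, as were the tests of their direction and of the set; the tests of low level and of neighbouring genes were chosen before.

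Of 34 measured genes of the HOX clusters, which encode position-specific transcription factors, 11 fell and 0 rose by limma in bulge cKO cells, while the others did not pass and included genes at or above 0 such as Hoxc10 (0.17) and Hoxa13 (0.14). As a set they had a camera p of 1.56e-06 downward at the preset correlation and of 0.0308 with an estimated one, which is not independent evidence for a set picked from these values. The lower ones included Hoxb6 (log2 difference -1.58, SE 0.36), Hoxd9 (-1.31, SE 0.20), Hoxb5 (-1.16, SE 0.19), Hoxb8 (-1.14, SE 0.26), Hoxd8 (-0.9, SE 0.18), Hoxa3 (-0.89, SE 0.11) and Hoxa5 (-0.87, SE 0.09). All 11 were higher in bulge WT than in interfollicular WT cells, Hoxb6 by a log2 difference of 3.1 and Hoxb5 by 2.46. The same bulge WT arrays enter both differences. Interfollicular cells in bulge cKO replicates 2 and 3 would also lower such genes, which was not tested for the HOX genes. In interfollicular cells 1 fell, Hoxc4 (-0.42). All 11 were also lower under cyclic loess and under median centring. All 11 kept a negative difference without cKO replicates 2 and 3, which for genes picked as lower is little evidence. Without these libraries 4 passed limma's threshold, Hoxa3 (-0.78), Hoxa5 (-0.72), Hoxb5 (-0.84) and Hoxb7 (-0.71). Among those that did not pass, Hoxb6 had -0.87, Hoxb8 -0.7, Hoxd9 -1.32 and Hoxa2 -0.23 (-0.38 with all arrays). Of the HOX genes, Hoxa5 passed the test of the difference between compartments (-0.81, adjusted p = 0.0375), while Hoxa3 had -0.88 (adjusted p = 0.0572).

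A hypothesis was that genes higher in interfollicular cKO cells rise from a low level in WT, measured in bulge WT so that the level and the change come from different arrays. Of 55 such genes, 54.5% lay below the median gene in bulge WT (exact binomial p = 0.59), so the test left this open.

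A second hypothesis was that neighbouring genes rise together. Among the 34 genes higher in both compartments 1 adjacent pair was found, Snrpn and Snurf, against a mean of 0.06 in 10000 random sets (permutation p = 0.0623), which left it open, and these genes share a transcript. In bulge cells 22 adjacent pairs were found among the higher genes (random mean 6.69) and 21 among the lower genes (5.88), each with a permutation p of 1e-04, the smallest that 10000 draws give, and an adjusted p of 0.00025. Those pairs hold gene families such as H2-Ab1 and H2-Aa, Hoxb7 and Hoxb8, or Col4a5 and Col4a6. Whether the H2 genes among them are linked to the targeted Ehmt2 locus was not tested. In interfollicular cells 2 pairs were found among the higher genes (permutation p = 0.014, adjusted p = 0.0233) and 0 among the lower ones. These pairs were Tmem176b with Tmem176a, and again Snrpn with Snurf, which share a transcript. The interfollicular p-value is therefore not separate evidence that neighbouring genes rise together.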
